A study of Homo sapiens with 6 samples.

How the data were processed

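Transcript levels were measured on 6 Illumina bead arrays, 3 from undifferentiated H1 cells (hESC) and 3 from H1 cells treated with Activin A (DE), all at passage 53. Each array was 1 biological replicate. Groups were taken from the activation label of each sample and replicate numbers from the sample descriptions; the titles of the DE samples carry numbers that are higher by 1. The numbers were not used to pair samples in the comparison reported.

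The deposited table holds 1 intensity per array for each of 15778 gene symbols, on a linear scale. Per the labels, biotin-labelled cRNA was stained with streptavidin-Cy3, and BeadStudio 3.0.14.0, R 2.9.0 and limma 2.18.1 were used by the authors, with no role stated for each tool. The sorted values of the 6 arrays differed by at most 0.0526 on the log2 scale at any rank, as after quantile normalization. The lowest value on each array was 26.6 units, so array background was not fully removed and the fold changes of dim genes are understated. How several probes of a gene were reduced to 1 value, and whether background was subtracted, is not stated. A second deposited table, of non-normalized probe intensities, was not used, because the names of its 6 columns match no sample. Detection p-values were not used.

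Symbols were updated with the gene table of the GRCh38.p14 reference, used for names only. Of the symbols, 13553 were current, 1532 were updated, 562 had no match, and 99 were older names of several genes. A further 25 and 7 kept the deposited name, because the current name had its own value or was shared. Coordinates were not used. Genes of the Y chromosome and XIST entered the fits and are not reported.

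Intensities were log2-transformed with no further normalization, filter or offset. The comparison of DE with hESC used R 4.3.3 and limma 3.58.1, with lmFit and eBayes (trend = TRUE), two-sided, without a replicate block. P-values were adjusted by the Benjamini-Hochberg method over all 15778 genes with a threshold of 0.05, and genes that changed at least 2-fold were also counted. There were 4 residual degrees of freedom and a median of 9.28 prior degrees of freedom. For a single gene, the smallest exact two-sided permutation p that 3 arrays against 3 can give is 0.1, so no permutation test of a single gene could pass the threshold. On simulated data of this size, all of 100 genes changed by 0.5 on the log2 scale were called, 6.1% of the calls were of unchanged genes, and 1 call was made when no gene was changed. The simulated noise was normal and independent between genes, and only a small share of genes was changed. These rates are therefore not the error rates of the real calls. The design fixed beforehand counted probes and then genes; since the table has 1 value per gene, the counts are of genes only.

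A total of 28 gene lists with 630 entries, drawn from textbook knowledge, was fixed before the data were examined: markers of pluripotency, definitive endoderm, primitive streak and other cell types, signalling pathways, adhesion and matrix, metabolism and stress, chromatin, imprinted, germline, cell cycle and housekeeping genes. Lists with at least 5 measured members were tested with limma's camera, two-sided, with a preset correlation of 0.01 between genes, and p-values were adjusted over the 28 lists. A further 7 lists were added later and are described under the other observations. The 4 of them written before their values were seen were adjusted among those 4, and no p-value is given for the 3 chosen afterwards. The genes named were fixed by a rule beforehand: the 12 largest increases and 12 largest decreases among genes past the threshold whose groups did not overlap; SOX17, FOXA2, CXCR4, GATA4, GATA6, POU5F1, NANOG and SOX2; up to 3 members of each list with the largest increase and 3 with the largest decrease past the threshold; and the first 2 of each list. Other genes are named with a statement that they were chosen after their values were seen, and all members of the added lists and single genes named there fall outside the rule.

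Alternatives changed 1 choice at a time: log2 of the value plus 16, normexp background with an offset of 50 or 16, median scaling, cyclic loess, only genes above the median of mean intensity, eBayes without a trend or robust, a replicate block, leaving out each array, an adjusted p under 0.01, limma's treat against a log2 change of 0.5, and for lists an estimated correlation and limma's fry. The normexp offset of 16 was chosen after seeing the data. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.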

Results

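The 6 arrays measured transcript levels in the human embryonic stem cell line H1 at passage 53. H1 is an established pluripotent line. In 3 biological replicates the cells were undifferentiated (hESC), and in 3 they had been treated with Activin A, a TGF-beta family ligand used to drive pluripotent cells towards definitive endoderm (DE), the embryonic layer that gives rise to gut, liver, pancreas and lung. The series set gene expression beside DNA methylation during this differentiation, and only expression was analysed here. Each array gave an intensity for the same 15778 genes. The median intensity lay between 55.2 and 55.3 units and the 95th percentile between 1083 and 1093 units on the 6 arrays, because the deposited values share one distribution. The 25th percentile was 38.9 to 39 units and the lowest value 26.6 units, so a gene near 40 units was close to the bottom of the scale, and its fold change is compressed by background. Replicates correlated at r = 0.996 to 0.997 across genes within each group, and arrays of different groups at r = 0.956 to 0.962. These are correlations across genes, which are not independent replicates. With 3 arrays per group, the number of arrays limits the precision, and the median standard error of a log2 change was 0.072.

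The comparison of DE with hESC asked which genes changed when the stem cells were differentiated. The 12 largest increases included 7 genes of the definitive endoderm list, and the 12 largest decreases included 4 metallothioneins and SOX2. FGF17, a fibroblast growth factor, rose from 88.6 ± 7.1 to 2280 ± 413 units (mean ± SD, n = 3), which is 25.5-fold. FREM1, an extracellular matrix protein, rose 23.5-fold. CER1, a secreted antagonist of Nodal, BMP and WNT, rose 22.5-fold, and the chemokine receptor CXCR4 rose 18.4-fold. The other genes among the 12 largest increases were ANKRD37, LEFTY2, LEFTY1, CCKBR, VWF, SOX17, GSC and ACKR3 (CXCR7 in the deposited table), with log2 changes from 4.22 down to 3.51. In the other direction MT1X, a metal-binding metallothionein, fell from 10183 ± 175 to 608 ± 158 units, which is 17.2-fold. CAMKV, a kinase-like protein of neurons, fell 13.2-fold and the chemokine CXCL12, a ligand of CXCR4, fell 7.95-fold. SOX2, CNMD (LECT1 in the table), MT1G, MT1A, TRIB3, INHBE, TENT5B (FAM46B in the table), CA4 and MT1H completed the 12 largest decreases, with log2 changes from -2.99 to -2.54. The MT1 genes are near-identical copies, as are LEFTY1 and LEFTY2. Probe sequences were not used here, so the values within each family are uncertain as measures of single genes.

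In total 3012 genes were higher and 3148 lower in DE at an adjusted p below 0.05 in limma's moderated test, or 39% of the genes tested. Most of these changes were small, with a median size of 0.44 on the log2 scale. At least 2-fold changes were called for 425 genes that rose and 338 that fell. The arrays of the groups did not overlap for 7549 genes, or 47.8%, where chance gives 10%. When limma's treat required a change beyond 0.5 on the log2 scale, 678 genes were higher and 712 lower.

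The definitive endoderm list had 29 measured genes, of which 27 rose and none fell, with a median log2 change of 2.58. SOX17, a transcription factor that specifies endoderm, rose from 129.6 ± 2.6 to 1714 ± 325 units, and FOXA2, a pioneer factor of endoderm, rose from 129.4 ± 9.2 to 1173 ± 51.9 units. The log2 changes were 3.71 (SE 0.11, adjusted p = 1.33e-11) and 3.18 (SE 0.080, adjusted p = 3.43e-12). GATA4 and GATA6, zinc finger factors of endoderm and heart, rose by 1.58 (SE 0.078) and 1.11 (SE 0.067) on the log2 scale. GATA4 started from 57.0 ± 2.7 units, and GATA6 went from 37.5 ± 2.0 units, at the bottom of the scale, to 81.1 ± 3.6 units, so their folds are compressed by background and were not ranked against those of SOX17 and FOXA2. TRPA1 and DKK1, named because they were the members not past the threshold and so chosen after their values were seen, stayed between 32.7 and 41.3 units on all 6 arrays (adjusted p = 0.129 and 0.171). The list was shifted upwards relative to other genes by limma's camera test (adjusted p = 1.74e-26), and the adjusted p was 0.0731 with an estimated correlation.

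**Figure D1:**
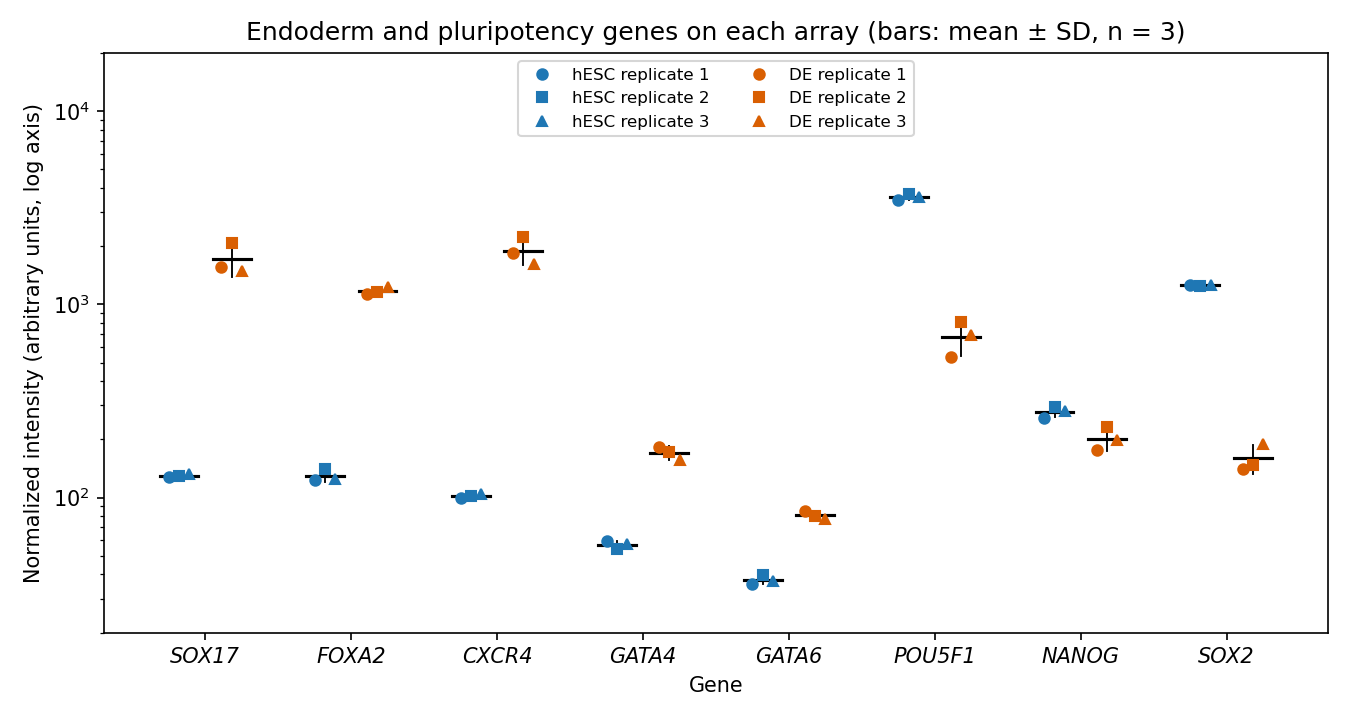
Normalized intensity on a log axis of 5 endoderm genes and 3 pluripotency genes, with 1 point per array (blue hESC, orange DE, shape giving the replicate), horizontal bars at the group means and vertical bars of 1 SD (n = 3). All DE arrays lie above all hESC arrays for SOX17, FOXA2, CXCR4, GATA4 and GATA6 and below them for POU5F1, NANOG and SOX2, and NANOG, at 201 units in DE against 278 in hESC, shows the smallest difference on the log axis.

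Of 33 measured genes of the pluripotency list, 25 fell, 3 rose and 5 did not pass; adjusted over the list alone, 25 fell and 4 rose. The median log2 change was -0.94. SOX2 fell from 1254 ± 11.2 to 159 ± 26.9 units, a log2 change of -2.99 (SE 0.10, adjusted p = 5e-11). POU5F1, which encodes OCT4, fell from 3592 ± 128 to 678 ± 138 units (log2 change -2.43, SE 0.12, adjusted p = 1.37e-09). The cell surface marker THY1 fell by 2.48 on the log2 scale. NANOG fell by 0.47 on the log2 scale (SE 0.099, adjusted p = 0.0014), from 278 ± 17.5 to 201 ± 27.8 units. POU5F1 and NANOG have close pseudogene or retrogene copies, which the array may not separate. The 3 members that rose were DPPA3 (log2 change 0.77), SALL4 (0.36) and GDF3 (0.38, adjusted p = 0.0462). The call of GDF3 ended when hESC replicate 1 or 2 or DE replicate 2 or 3 was left out, with adjusted p between 0.12 and 0.18, and when the variance was moderated without a trend (adjusted p = 0.0517). The list was shifted downwards by camera (adjusted p = 1.38e-11; adjusted p = 0.131 with an estimated correlation).

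Genes of the primitive streak moved in both directions. Of 14 measured members 8 rose and 3 fell; adjusted over the list alone, 8 rose and 4 fell. The T-box factor EOMES rose from 366 ± 25.8 to 3944 ± 68.6 units, the homeobox gene MIXL1 from 255 ± 36.9 to 1879 ± 89.2 units, and the organizer gene GSC from 54.7 ± 14.6 to 650.4 ± 84.6 units. TBXT (Brachyury), a marker of streak and nascent mesoderm, fell from 146.7 ± 8.9 to 78.6 ± 2.0 units, and MESP1, a factor of early cardiac mesoderm, fell from 181 ± 17.6 to 67.7 ± 9.3 units. The log2 changes of these 2 genes were -0.90 (SE 0.073) and -1.42 (SE 0.10). The list was shifted upwards (camera adjusted p = 0.0167; adjusted p = 0.512 with an estimated correlation), and its increases include genes it shares with the endoderm list. Of 23 mesoderm genes, 3 rose and 7 fell, without a call for the list (camera adjusted p = 0.29). HAND1, a factor of lateral mesoderm and trophoblast, fell from 2183 ± 92.9 to 660 ± 156 units, whereas FOXC1, a forkhead gene of mesoderm, rose from 286 ± 38.3 to 1247 ± 229 units. PDGFRA rose by 0.43 on the log2 scale. TBX6 had a log2 change of -0.01 (adjusted p = 0.902), but it lay near the bottom of the scale, at 39.3 ± 1.4 units in hESC.

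The Nodal and Activin pathway list had 13 of 23 measured genes higher and 2 lower in DE. The secreted Nodal inhibitors rose most. LEFTY2 went from 717 ± 31.2 to 12863 ± 887 units and LEFTY1 from 796 ± 86.8 to 11426 ± 107 units. SMAD4, the common SMAD, fell by 0.41 on the log2 scale. Camera called the list upwards with an adjusted p of 0.000326, and the adjusted p was 0.131 with an estimated correlation. Its increases include CER1, LEFTY1 and LEFTY2, which it shares with the endoderm list. The median log2 change of the list was 0.285 and its mean 0.805. Of 30 WNT pathway genes, 15 rose and 6 fell; adjusted over the list alone, 15 rose and 8 fell. The receptors FZD5 and FZD8 rose by 2.51 (SE 0.11) and 2.40 (SE 0.080) on the log2 scale, and the secreted WNT inhibitor SFRP1 rose from 757 ± 81.9 to 4230 ± 199 units. Its paralog SFRP2 fell from 307 ± 11.5 to 64.7 ± 3.3 units, and the ligands WNT5A and WNT5B fell by 0.75 and 0.94 on the log2 scale. The WNT list was called upwards (camera adjusted p = 0.0234; adjusted p = 0.364 with an estimated correlation).

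Members of the BMP, FGF and Notch lists changed in both directions, and none of these lists was called. In the BMP list 6 of 21 genes rose and 8 fell (camera adjusted p = 0.84). ID1 and ID3, direct targets of BMP signalling, fell from 1941 ± 72.4 to 402 ± 26 units and from 1143 ± 114 to 418 ± 17.1 units, and the homeobox gene MSX1 fell by 2.32 on the log2 scale. The ligand BMP2 rose from 213 ± 14.3 to 892 ± 79.9 units, and the antagonists FST and NOG rose by 1.72 and 1.05 on the log2 scale. In the FGF and ERK list 6 of 21 genes rose and 9 fell (10 fell when adjusted over the list alone; camera adjusted p = 0.293). FGF8 rose by 2.05 and the phosphatase DUSP4 by 2.32 on the log2 scale, while FGF2, the growth factor of pluripotent cell culture, fell by 1.61, FGF19 by 2.05 and the immediate early gene FOS by 2.33. In the Notch list 4 of 16 genes rose and 7 fell (camera adjusted p = 0.249). The ligand JAG2 rose by 1.05 and JAG1 fell by 1.45 on the log2 scale, and the target gene HEY2 fell from 990.1 ± 58.3 to 174 ± 16.7 units.

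Markers of other cell types gave a mixed picture. Of 20 extraembryonic endoderm genes, 11 rose and 4 fell. The apolipoprotein genes APOA2 and APOA1 rose from 688 ± 117 to 2287 ± 54.5 units and from 416 ± 91.4 to 932 ± 41.6 units, and the basement membrane collagen COL4A1 rose by 1.03 on the log2 scale. PTH1R, a receptor of parietal endoderm, fell by 1.80 and the transport protein gene TTR by 1.07 on the log2 scale. SOX7 and AFP, markers of this tissue, had log2 changes of -0.01 and -0.04 (adjusted p = 0.953 and 0.908). SOX7 lay near the bottom of the scale, at 40.5 ± 3.2 units in hESC, whereas AFP was at 366 ± 100 units. Camera called the list upwards with an adjusted p of 0.0392, but the adjusted p was 0.412 with an estimated correlation and 0.0588 without DE replicate 2. Its increases include genes it shares with the basement membrane and collagen list, such as COL4A1. Of 23 genes of later gut, liver and pancreas, 3 rose and 3 fell (camera adjusted p = 0.84). ALB had a log2 change of 0.03 (adjusted p = 0.844) but lay near the bottom of the scale, at 40.3 ± 3.3 units in hESC. The intestinal factor CDX2 fell by 0.62 on the log2 scale. Of 22 neuroectoderm genes, 5 rose and 5 fell (6 rose when adjusted over the list alone; camera adjusted p = 0.84). SOX3 fell from 220.5 ± 10.2 to 66.3 ± 8.3 units and TUBB3, a neuronal tubulin, rose from 691 ± 31.6 to 1638 ± 33.0 units. Of 19 trophoblast genes, 3 rose and 4 fell (5 fell when adjusted over the list alone; camera adjusted p = 0.678), with TFAP2C down by 2.08 and GATA3, which is also on the endoderm list, up by 0.74 on the log2 scale.

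In the endothelial and blood list 4 of 19 genes rose and 1 fell; adjusted over the list alone, 3 rose and 1 fell (camera adjusted p = 0.326). Von Willebrand factor, VWF, rose from 160.1 ± 4.3 to 2151 ± 246 units. PECAM1 and CDH5, junction proteins of endothelium, had log2 changes of 0.12 and -0.01 (adjusted p = 0.222 and 0.879). Both lay near the bottom of the scale, at 46.8 ± 0.3 and 38.1 ± 1.1 units in hESC, so their lack of change says little. The receptor TEK rose from 119.9 ± 9.7 to 189.3 ± 6.9 units and HBG1 rose by 0.99 on the log2 scale, while the receptor KDR fell by 0.60. In the fibroblast list 4 of 16 genes rose and 1 fell (camera adjusted p = 0.249, and 0.0404 without DE replicate 1). LOX, an enzyme that crosslinks collagen, rose by 1.63 and TAGLN, an actin-binding protein of smooth muscle, by 1.32 on the log2 scale. DE replicate 1 was low in several genes of this list but not in all. TAGLN was highest there, at 2994 units against 2714 and 2286 units in DE replicates 2 and 3, and S100A4 lay between the other DE arrays. COL3A1, singled out after its values were seen, was 239 units in DE replicate 1 against 430.1 and 553 units in DE replicates 2 and 3, and DCN, singled out in the same way, was 49.8 units against 66.2 and 99.6 units. The log2 change of COL3A1 was 0.58 over all arrays (adjusted p = 0.054) and 0.93 without DE replicate 1 (adjusted p = 0.000132), and that of DCN was 0.46 (adjusted p = 0.056) and 0.69 (adjusted p = 0.00131). Both genes were singled out with DE replicate 1 low, so a smaller p without it was largely built in. With all arrays COL3A1 passed with cyclic loess (adjusted p = 0.0463). COL3A1 and DCN passed among genes above the median intensity (adjusted p = 0.0324 and 0.0341) and with the replicate block (adjusted p = 0.00112 and 0.00335). Neither passed with log2(value + 16), normexp, median scaling, or eBayes without a trend or robust. The imprinted gene H19 was 225 units against 580.5 and 578 units.

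Cell adhesion and matrix genes changed as follows. In the epithelial list 7 of 17 genes rose and 3 fell. The keratin genes KRT19 and KRT8 rose from 1830 ± 248 to 8036 ± 1516 units and from 814 ± 40.4 to 2528 ± 321 units. CDH1, which encodes E-cadherin, fell from 2334 ± 211 to 1225 ± 177 units. EPCAM had a log2 change of -0.01 (adjusted p = 0.931), but it was dim, at 64.1 ± 9.9 units in hESC and 63 ± 1.1 units in DE. The list was not called (camera adjusted p = 0.201); its median log2 change was -0.001 and its mean 0.29, in the direction of the test. In the mesenchymal list 8 of 14 genes rose and 3 fell. CDH2, which encodes N-cadherin and is also on the endoderm list, rose from 2562 ± 144 to 7996 ± 375 units, ITGA5 rose by 1.19 and vimentin, VIM, by 0.95 on the log2 scale. SNAI2, a transcriptional repressor of CDH1, fell by 0.69. The mesenchymal list was called upwards at an adjusted p of 0.0467 by camera. The adjusted p was 0.412 with an estimated correlation, 0.0507 with the replicate block, and 0.0516, 0.0588 and 0.0846 without hESC replicate 1, DE replicate 2 and DE replicate 3. In the basement membrane and collagen list 10 of 24 genes rose and 2 fell (11 rose when adjusted over the list alone). COL5A2 rose from 851 ± 43.7 to 3508 ± 83.7 units and COL4A6 from 64.6 ± 6.2 to 196 ± 22.1 units, while the laminin gene LAMC1 fell by 0.96 on the log2 scale. COL1A1 and COL1A2 had log2 changes of -0.05 and 0.13 (adjusted p = 0.776 and 0.231). Camera called the list upwards at an adjusted p of 0.0063, with an adjusted p of 0.364 with an estimated correlation.

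More genes rose than fell in the lists for hypoxia and for glycolysis. Of 14 hypoxia genes 10 rose and none fell, with a median log2 change of 1.19 (camera adjusted p = 5.19e-06; adjusted p = 0.372 with an estimated correlation). ANKRD37, a target of HIF1A, rose from 63.5 ± 2.4 to 1227 ± 432 units, BNIP3, a mitophagy receptor, from 1930.0 ± 81.0 to 6555 ± 65.1 units and the hexokinase gene HK2 from 72.0 ± 4.3 to 294 ± 43.2 units. The 4 members not past the threshold were VEGFA, CA9, PDK1 and EGLN3 (the last 2 named after their values were seen), with log2 changes between -0.05 and 0.06. Of 20 glycolysis genes 14 rose and 3 fell, with a median log2 change of 0.53 (camera adjusted p = 0.000132; adjusted p = 0.519 with an estimated correlation). The pyruvate kinase gene PKM rose from 381 ± 20.1 to 1167 ± 163 units and the lactate dehydrogenase gene LDHA from 4088 ± 417 to 10179 ± 676 units, and the muscle phosphofructokinase gene PFKM fell by 0.41 on the log2 scale. The DE arrays differed among themselves in these genes. Across the 31 genes of both lists the median deviation from the other 2 DE arrays was 0.30 for DE replicate 2, -0.23 for DE replicate 1 and -0.07 for DE replicate 3 on the log2 scale.

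**Figure D2:**
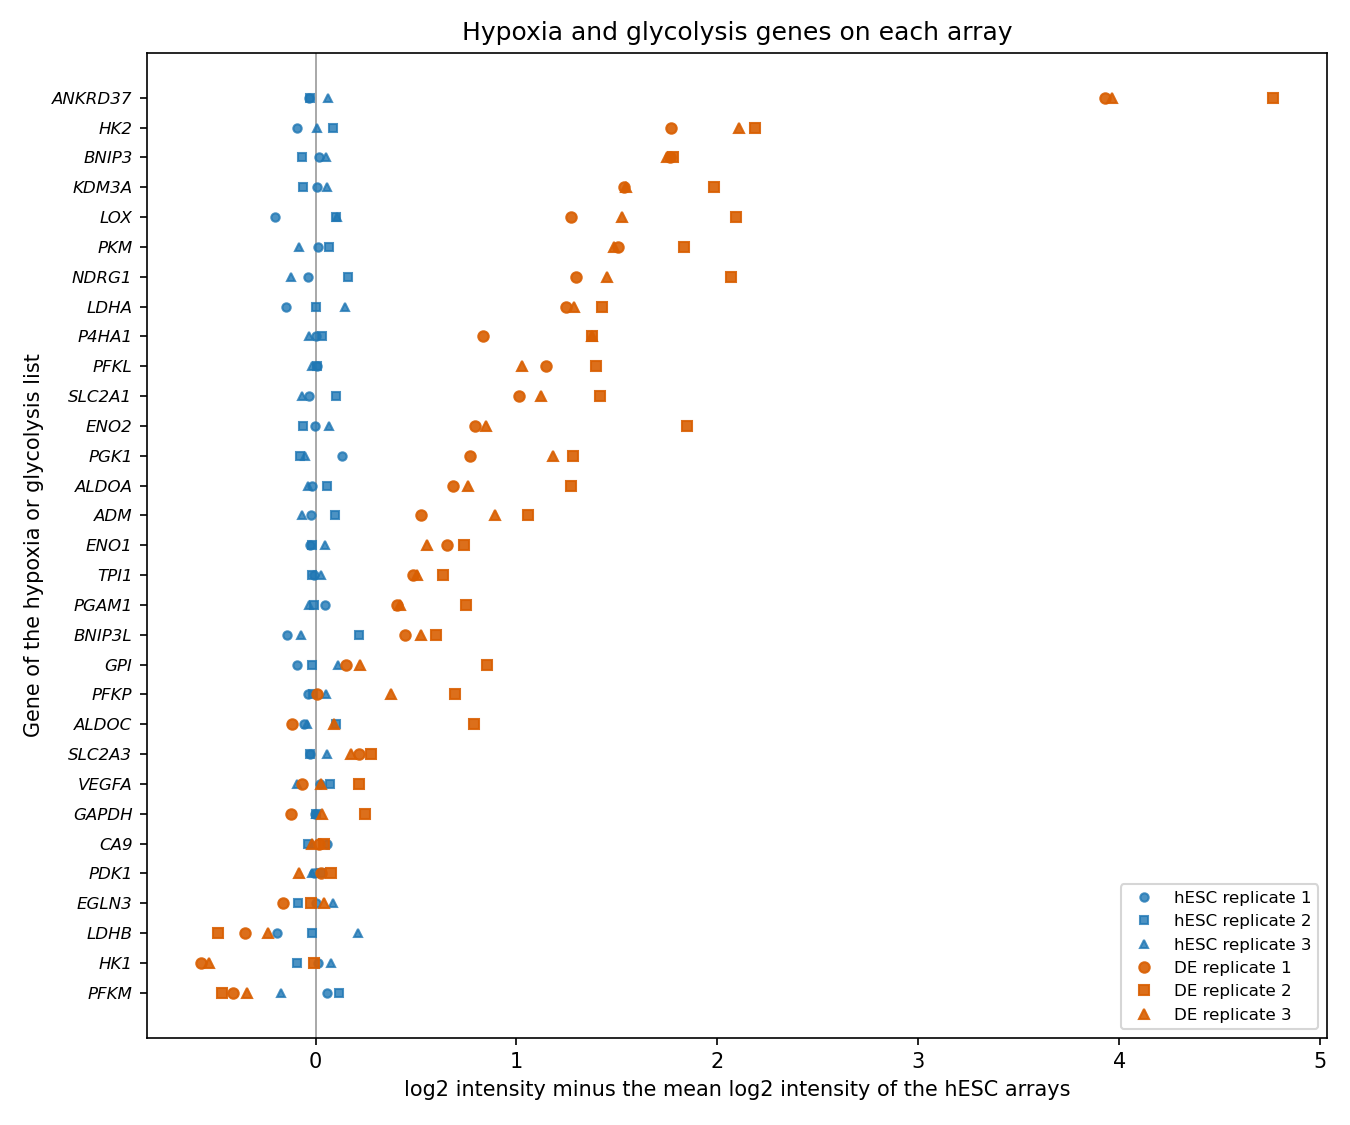
Log2 intensity of each of the 31 measured hypoxia and glycolysis genes on each array, minus the mean log2 intensity of that gene on the hESC arrays (blue hESC, orange DE, shape giving the replicate). For 21 of the 31 genes all DE arrays lie above all hESC arrays, and DE replicate 2 has the highest value for most of the genes that rose, including ANKRD37 and LOX.

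More genes fell than rose in the lists for cell cycle and for unfolded protein and amino acid stress. Of 27 cell cycle genes none rose and 17 fell, with a median log2 change of -0.38 (camera adjusted p = 0.000121; adjusted p = 0.131 with an estimated correlation). The replication helicase genes MCM3 and MCM5 fell from 3327 ± 294 to 1620 ± 54.0 units and from 621 ± 27.4 to 337 ± 38.0 units, and the kinetochore gene CENPF fell by 0.82 on the log2 scale. MKI67, a marker of proliferating cells, had a log2 change of 0.01 (adjusted p = 0.908). It lay near the bottom of the scale, at 48.4 ± 2.1 units in hESC and 48.8 ± 2.0 units in DE, so its value says little about proliferation. In the list for unfolded protein and amino acid stress 10 of 16 genes fell and 3 rose (4 rose when adjusted over the list alone), with a median log2 change of -0.82. The pseudokinase gene TRIB3 fell from 2073 ± 223 to 309 ± 18.2 units, the transcription factor gene CEBPB from 3218 ± 95.4 to 865 ± 25 units, and PSAT1, an enzyme of serine synthesis, from 2048 ± 108 to 707 ± 18.6 units. The members that rose were HSPA5, the chaperone of the endoplasmic reticulum, from 232 ± 20.8 to 511 ± 103 units, its cochaperone DNAJB9 by 0.74 and the transcription factor ATF4 by 0.36 on the log2 scale. Camera called this list downwards with an adjusted p of 0.00321, and the adjusted p was 0.131 with an estimated correlation.

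Chromatin genes changed one by one without a call for their lists. In the DNA methylation list 5 of 19 genes rose and 6 fell; adjusted over the list alone, 6 rose and 6 fell (camera adjusted p = 0.84). The de novo methyltransferase gene DNMT3B fell from 911 ± 16.4 to 251 ± 26.2 units (log2 change -1.86, SE 0.086, adjusted p = 8.75e-10). The maintenance methyltransferase gene DNMT1 fell from 2309 ± 143 to 1377 ± 44.2 units, and HELLS, a chromatin remodeller needed for DNA methylation, fell by 0.54 on the log2 scale. DNMT3L, a cofactor of the de novo enzymes, rose from 38.9 ± 2.1 to 58.5 ± 3.7 units, near the bottom of the scale, and ZBTB33, which encodes the methyl-CpG binding protein Kaiso, rose from 371 ± 19.4 to 642 ± 7.3 units. The median log2 change of this list was 0.06 and its mean -0.07, so that they differ in sign. In the Polycomb and trithorax list 6 of 26 genes rose and 11 fell (7 rose when adjusted over the list alone; camera adjusted p = 0.29). PHC1 fell from 652 ± 32.3 to 170 ± 4.5 units and JARID2 from 2527 ± 323 to 1138 ± 88.4 units, both also on the pluripotency list, while the histone demethylase gene KDM6B rose by 0.62 on the log2 scale.

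Of 39 HOX genes 5 rose and 4 fell; adjusted over the list alone, 2 rose and 3 fell (camera adjusted p = 0.84). HOXB2 fell from 183 ± 7.7 to 90.0 ± 10.2 units and HOXD1 rose from 38.4 ± 2.3 to 69.6 ± 3.6 units, and the median intensity of the list was 38.7 units. Its median log2 change was 0.02 and its mean -0.008. Of 22 imprinted genes 6 rose and 5 fell; adjusted over the list alone, 7 rose and 5 fell (camera adjusted p = 0.555). PEG10 rose from 52.3 ± 0.9 to 148 ± 7.0 units, DLK1 from 246 ± 62.7 to 680 ± 207 units and NDN by 0.99 on the log2 scale, and SNRPN fell from 5633 ± 69.3 to 3576 ± 135 units. H19 had a log2 change of 0.15 (adjusted p = 0.714) over all arrays, and of 0.61 (adjusted p = 0.000359) without DE replicate 1. Of 18 germline genes 1 rose and 3 fell, among them TEX15, by 0.62 on the log2 scale (camera adjusted p = 0.444). In the housekeeping list 4 of 14 genes rose and 6 fell (camera adjusted p = 0.473). PGK1, also a glycolytic enzyme, rose by 1.08 and ACTB by 0.27, HPRT1 fell by 0.91, and GAPDH had a log2 change of 0.05 (adjusted p = 0.656).

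**Figure D3:**
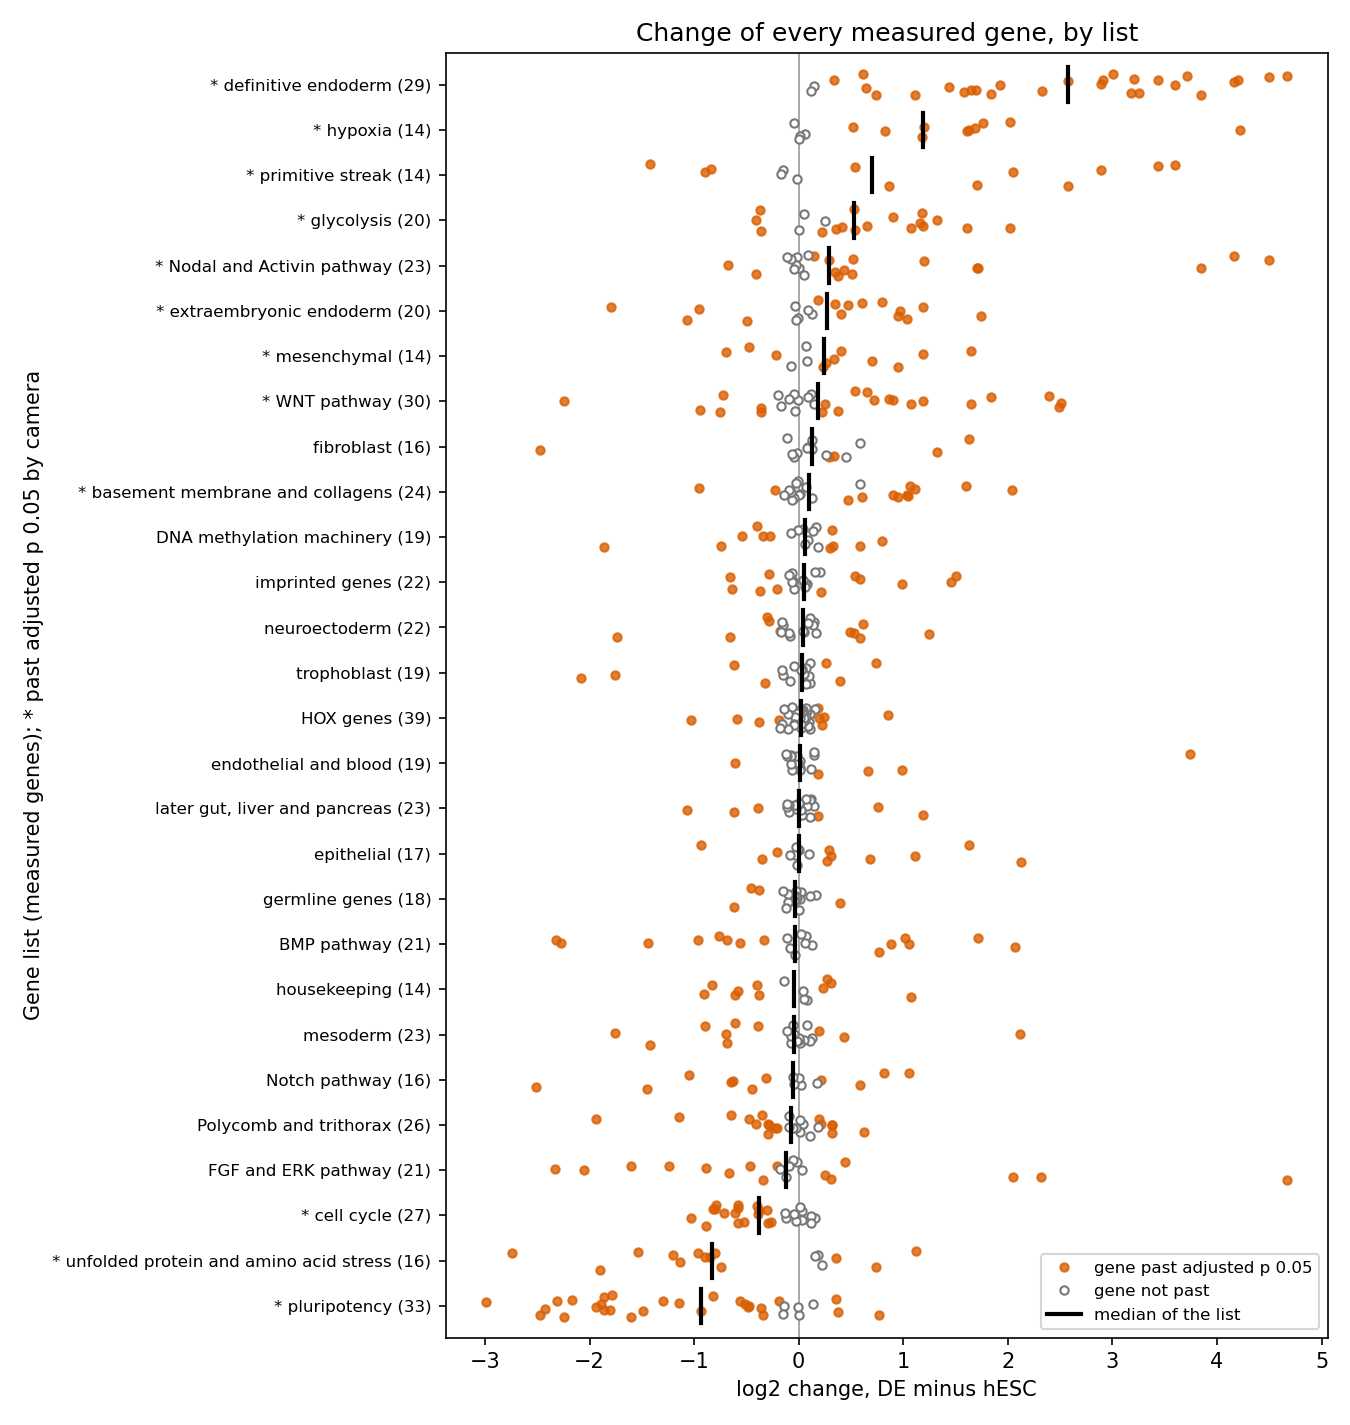
Log2 change (DE minus hESC) of every measured gene of the 28 lists, with 1 point per gene, filled where limma's adjusted p was below 0.05, and a black bar at each list's median; stars mark the lists called by camera. Definitive endoderm has the highest median, 2.58, and pluripotency the lowest, -0.94, and the HOX genes cluster around 0.

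Of the 28 lists tested, 9 were called upwards and 3 downwards by camera with a preset correlation of 0.01 between genes. None kept an adjusted p below 0.05 with a correlation estimated from the residuals, a test with 4 degrees of freedom, although 5 lists had an unadjusted p below 0.05 there and limma's fry, which asks whether a list's genes move on balance one way, called 21 lists. Counts adjusted over the list alone equalled the counts over all genes for each of the 28 lists where no such count is given.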

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

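No called gene changed sign with log2(value + 16), normexp, median scaling, cyclic loess or without any 1 array; other alternatives leave log2 changes as they were. Of 6160 calls 99.4% to 99.9% were kept with log2(value + 16), normexp with an offset of 50 or 16 (the latter chosen after seeing the data), median scaling and robust moderation. The share was 97.8% without a trend, 97.5% with cyclic loess, 95.8% with the replicate block and 86.6% to 90.4% without any 1 array, where fewer arrays were fitted. Among genes above the median intensity 5082 of the calls were tested, and all 5082 were kept. Calls were more frequent among these genes, which loosens the adjustment of p, so keeping them was largely built in. Median scaling could likewise change little, because the arrays already shared one distribution. Leaving out 1 array gave 2628 to 2812 higher and 2832 to 2987 lower genes, and an adjusted p under 0.01 gave 2287 and 2536. Limma's treat against a log2 change of 0.5 gave 678 higher and 712 lower genes, since most changes were smaller than its bound. Changes of at least 2-fold were called for 338 to 509 higher and 248 to 452 lower genes, lowest with normexp and an offset of 50 and highest with an offset of 16. The replicate block gave 2910 and 3070; under the replicate block COL3A1 and DCN gained a call (adjusted p = 0.00112 and 0.00335; also 0.0324 and 0.0341 among genes above the median intensity, and 0.0463 for COL3A1 with cyclic loess), CALR lost one (0.0515), and the mesenchymal list lost its call (0.0507). Deviations from the group means correlated at 0.0413, -0.0907 and -0.0448 across genes between arrays of the same number in the descriptions; pairing by title was not tested. No scaling moved the median of all genes by more than 0.1 on the log2 scale.

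With an estimated correlation between genes none of the 12 called lists passed: the adjusted p was 0.0731 for definitive endoderm, 0.131 for pluripotency, the Nodal and Activin pathway, cell cycle, and unfolded protein and amino acid stress, 0.364 for the WNT pathway and basement membrane, 0.372 for hypoxia, 0.412 for extraembryonic endoderm and mesenchymal, 0.512 for primitive streak and 0.519 for glycolysis. Of the added lists, cholesterol synthesis (0.0645) and oxidative phosphorylation (0.268) lost their calls with it (adjusted over the 4 written before their values were seen, as below). That test has 4 degrees of freedom. Fry, which compares a list with no other genes, also called endothelial and blood (0.000727), epithelial (0.00348), Notch, Polycomb and imprinted genes (each 0.00416), trophoblast and housekeeping (each 0.0044), mesoderm (0.0178), germline genes (0.0342) and the added retinoid list (0.0049). It gave the BMP (0.61), DNA methylation (0.4) and added interferon lists (0.319) the opposite direction, past no threshold. Among genes above the median intensity, with fewer genes tested, extraembryonic endoderm (0.0514) and mesenchymal (0.206) lost their calls, and neuroectoderm (0.916) and HOX genes (0.723) turned direction without a call. Mesenchymal also lost its call with log2(value + 16) (0.0522) and normexp with an offset of 50 (0.0516); the cause was not tested.

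Without any 1 array the adjusted p of the mesenchymal list ranged from 0.0266 to 0.0846, past the threshold except without hESC replicate 1, DE replicate 2 or DE replicate 3. Extraembryonic endoderm ranged from 0.0266 to 0.0588 and lost its call without DE replicate 2; fibroblast ranged from 0.0404 to 0.423 and gained a call without DE replicate 1. DNA methylation and HOX genes each ranged from 0.707 to 0.92; the first turned direction without hESC replicate 2 or DE replicate 2, the other without DE replicate 3. The interferon list ranged from 0.73 to 0.993 and turned direction without hESC replicate 3 or DE replicate 2. The other 10 called lists of the 28 kept their call and direction without any 1 array. Among 182 genes named by the rule, 158 were past the threshold, 14 of these lost the call under some alternative, and WNT3A and H19 gained one. Not run were no normalization between arrays, a filter on detection p, the slide as a block and averaging of probes, which need the table not used; the authors' table, planned as an alternative, became the source.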

Other observations

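The metallothionein, antigen presentation and serine and glycine lists, the single genes named here other than SLC30A1 and SLC39A10, and the tests on NANOG were chosen only after their results were seen. No p-value is given for these lists. Of 11 metallothioneins, small proteins that bind zinc and copper, 8 fell and none rose, and MT3, MT1B and MT4, all dim, did not pass (median log2 change -2.32, n = 3 arrays per group). MT3 passed upwards without hESC replicate 2 (adjusted p = 0.0369). MT2A fell from 3441 ± 185 to 687 ± 16.8 units, and MT1M fell by 0.97 on the log2 scale. Of 17 genes of serine, glycine and one-carbon metabolism 12 fell and none rose (median -0.65). GLDC, which cleaves glycine, fell from 1834 ± 23 to 392 ± 51.1 units, and PHGDH, the entry enzyme of serine synthesis, from 16507 ± 226 to 9181 ± 353 units. Of 19 antigen presentation genes 11 fell and 1 rose (median -0.35). The peptide transporter TAP1 fell from 433 ± 16.9 to 94.2 ± 6.5 units and the proteasome subunits PSMB10 and PSMB8 fell by 1.55 and 1.16 on the log2 scale. B2M fell by 0.58. CALR, which rose by 0.23, lost its call with the replicate block (adjusted p = 0.0515) and without hESC replicate 2 or 3 or DE replicate 1 or 3 (adjusted p = 0.0692 to 0.122).

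The other 4 added lists were written before their values were seen, and their p-values are adjusted over these 4. Of 21 cholesterol synthesis genes 12 rose and 2 fell, and 14 rose and 2 fell adjusted over the list alone (median log2 change 0.26, camera adjusted p = 0.000523; adjusted p = 0.0645 with an estimated correlation). HMGCS1, an early enzyme of the pathway, rose from 419 ± 29.3 to 969 ± 67.2 units, while SC5D fell by 0.67 on the log2 scale. Of 34 oxidative phosphorylation genes 21 fell and 3 rose, also adjusted over the list alone (median -0.26, camera adjusted p = 0.000523; adjusted p = 0.268 with an estimated correlation). ATP5MC1, a subunit of ATP synthase, fell from 673 ± 30.3 to 331 ± 38.5 units, and the complex I subunit NDUFV1 fell by 0.64, whereas NDUFB3, UQCRC1 and SDHC rose by 0.56, 0.56 and 0.39. Of 22 interferon response genes 7 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.923; adjusted p = 0.944 with an estimated correlation), with MX1 down from 214 ± 17.6 to 79.8 ± 7.8 units. Of 18 retinoid genes 8 rose and 4 fell, and 8 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.533; adjusted p = 0.654 with an estimated correlation), with the receptors RARB and RXRA up by 0.75 and 0.73 and the reductase DHRS3 down from 213.5 ± 4.0 to 123 ± 15.1 units. Outside these lists, PFKFB4, which regulates glycolysis, rose by 3.37, the lactate transporter SLC16A3 by 3.17 and the collagen lysyl hydroxylase PLOD2 by 2.87 on the log2 scale.

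The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 6160 genes against at most 0 in the others, and 12 lists against at most 8, so that 1 of the 10 splits, the real one, gave as many in each case. Every other split put DE and hESC arrays together on both sides. The difference between the groups then widened the spread within each side, which made few gene calls certain beforehand, and part of it remained between the sides. The counts of the other splits are therefore not those of data without a group difference.

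Hypoxia and glycolysis genes were higher in DE, with a median log2 change of 0.65 over the 31 measured members of both lists, though neither list passed with an estimated correlation (adjusted p = 0.372 and 0.519). DE replicate 2 alone does not account for this: without it the median was 0.605, and hypoxia (adjusted p = 1.43e-06) and glycolysis (adjusted p = 0.000246) kept their calls. Among 10000 random lists matched on intensity the highest median was 0.355 and 0 were as high (1e-04 is the smallest share the draws can give). Other genes of like intensity thus did not rise as a set. The arrays already shared one distribution, which kept such medians small beforehand, so the draws cannot decide on the normalization of bright genes. They also took genes as independent, whereas the estimated correlations between genes were 0.429 (hypoxia) and 0.513 (glycolysis). A response to low oxygen in the DE cultures is a candidate explanation that stays open. Targets commonly used as its markers did not pass: VEGFA (74.9 ± 4.4 to 78.2 ± 7.9 units) and CA9 (47.9 ± 1.6 to 48.4 ± 1.0 units). CA9 lay near the bottom of the scale and decides nothing. VEGFA was dim as well. It started above ANKRD37 (63.5 ± 2.4 units) and HK2 (72.0 ± 4.3 units), which rose. Intensities of different genes come from different probes, and probe sequences were not used, so the lack of change of VEGFA is weak evidence. Of the 14 hypoxia genes 10 rose, none fell and 4 did not pass. Medium, cell density and time in culture went with the groups and were not tested.

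The fall of 8 metallothioneins may reflect lower activity of MTF1, the transcription factor that senses zinc. SLC30A1, a zinc exporter and the other textbook target of MTF1, fell with a log2 change of -1.206 (SE 0.086, adjusted p = 6.9e-08), as this explanation needs. SLC39A10, a zinc importer that MTF1 represses, fell by 0.76 (adjusted p = 4.33e-06), which goes against it, so single genes leave it open. Shared sequence between metallothionein probes and a difference in zinc between the media were not tested.

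NANOG fell less than most of the pluripotency list, to 72.1% of its hESC intensity against 18.6% for POU5F1 and 12.6% for SOX2. A background at the 25th percentile of each array is argued against as the whole cause. After subtracting it the log2 change of NANOG was -0.569 (SE 0.155, not moderated). The median of the 33 measured members was -0.966 or -2.047. The first counts the 4 members not above that percentile on every array, all lower in DE, as the highest, the second as the lowest. Against -0.966 the margin is narrow for so few arrays, and a higher background of the NANOG probe was not examined. Undifferentiated cells left in the cultures would bring POU5F1 and SOX2 in the same share as NANOG, yet the higher of the upper 95% bounds of these 2 shares was 22.2%, against a lower bound of 62.2% for NANOG, so such cells are argued against as its whole source. Expression of NANOG in the DE cells may remain, and a signal from NANOG pseudogenes stays open, since probe sequences were not used.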
